A study of Homo sapiens with 2 samples.

How the data were processed

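RNA from the breast cancer cell line labelled 231 (the usual short name of MDA-MB-231, an oestrogen receptor negative line) was sequenced in 2 libraries. One library came from cells carrying the pcDNA3.1 plasmid, a mammalian expression vector, and the other from cells overexpressing HOXC-AS3, a long non-coding RNA. Groups were taken from the genotype label of each sample, and the columns of the tables were matched to samples by the library names in the sample descriptions. There was 1 library per group, so no test between groups was possible and every difference describes these libraries and not the conditions. Per the labels' protocols, RNA was taken up in Trizol, ribosomal RNA was removed with a Ribo-Zero kit, and strand-specific TruSeq total RNA libraries were made. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, bedtools, deepTools and HOMER, and the genome build hg19, with no role for each. The program that computed expression values and p-values, and whether it used strand, is not given in the sources used here.

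The authors deposited expression as FPKM, fragments per kilobase of transcript scaled to the number of mapped fragments, 1 value per gene and library. Per the file headers, the tables hold protein-coding genes with a fold of at least 2.0 between the libraries and an FPKM of at least 0.1 in at least 1 library, and the p-value limit was 1.0, so no gene was removed for its p-value. All 3931 rows carried the protein-coding biotype, the smallest fold was 2.00 and the smallest value in the higher library 0.100. The deposited fold and log2 fold columns, per the file headers, hold the ratio of the FPKM values, and the deposited log2 score runs far beyond a usual log2 range where an FPKM is an estimate next to 0; neither column was used, and ratios were recomputed from FPKM. The p-value and adjusted p-value per gene are the authors' own, deposited with the tables; they compare 1 library with 1 library, rest on the authors' model of the spread, and are quoted only as the authors'. HOXC-AS3 itself is not protein-coding and was not analysed here. A gene without a row may have differed by less than 2-fold, may have been under the FPKM limit, or may not have been measured, and these cannot be separated.

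FPKM of rows with the same symbol were added (6 symbols had more than 1 row), giving 3925 symbols. Log2 ratios are log2 of HOXC-AS3 FPKM plus 1 over vector FPKM plus 1; the pseudocount of 1 shrinks the ratios of low genes. Genes with an FPKM of at least 1 in at least 1 library were kept (2707), and a log2 ratio of at least 1 in size was counted as 2-fold. Rescaling of the libraries (centring on the median gene or trimmed means) was planned and not run, since genes that differed by less than 2-fold were not analysed here and the ratio of the typical gene is therefore unknown. Exact zeros are given as "listed at 0", without a fold, because some genes used by every cell, such as LIAS, were listed at 0 as well.

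Depth was not stated and was estimated from the values. In genes with 1 annotated transcript in GENCODE 29 (333 genes; 97.5% of the gene identifiers matched that release), FPKM multiplied by transcript length should fall on whole multiples of the worth of 1 fragment. The step that best fitted values between 0.05 and 1.5 FPKM kb was 0.192 in the vector library (bootstrap 95% interval 0.189 to 0.195) and 0.186 in the HOXC-AS3 library (0.183 to 0.190). This corresponds to 5220000 fragments (5130000 to 5310000) in the vector library and 5390000 (5280000 to 5460000) in the HOXC-AS3 library. An FPKM of 1 in a 2-kb transcript thus rests on about 10.4 and 10.8 fragments. These are estimates. They assume that the annotated lengths are close to those the authors used. Only steps from 0.12 to 0.4 FPKM kb were tried, so a depth beyond the range of those steps could not have been found. The bootstrap intervals show how the fitted step varied with the genes drawn. Binomial intervals of fragment counts given below cover the counting error of independent fragments only, and no spread between replicate libraries. Fragments copied by PCR are not independent molecules, so the intervals may be too narrow even for counting error. Binomial intervals of list shares treat genes as independent draws and do not measure counting error.

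The design fixed in advance mainly assumed tables of all measured genes. The tables used here hold only genes already selected at 2-fold, so random lists were drawn from selected genes alone. The written design names this case for the share of higher members but not for the median log2 ratio. Before the data were examined, 36 gene lists, the rule for named genes and the alternatives were fixed. Named were the HOXC genes present, the 12 genes with the largest and the 12 with the smallest ratio among genes at FPKM 1 or more in both libraries, up to 4 members per direction of each list described, and up to 5 genes per direction listed at 0 in 1 library. For lists with at least 5 members above the FPKM minimum, the share of higher members and the median log2 ratio were placed among 10000 random lists of the same size drawn from the listed genes and matched on deciles of mean FPKM. These percentiles are descriptions of the 2 libraries and no p-values, since genes are not replicates. On simulated lists of 15 genes from the same pool of 2707, 7.00% of 200 lists without an effect fell outside the central 95% range. Of lists with 90% higher members, 93.5% lay above that range. These rates were not measured for other sizes. The lists placed held 5 to 9 members above the FPKM minimum, or 23 for the KRAB zinc finger genes. The median step was recovered within 0.500% for 3 known steps, all inside the range of steps tried. Those values were simulated as whole counts without selection at 2-fold and with small random errors of length. The recovery therefore does not check whether the annotated lengths were close to those the authors used. The number of simulated lists was raised once, after a first run with fewer. Alternatives were pseudocounts of 0.1 and 0.01, other FPKM minimums, a fold of 4 and other handling of repeated symbols; one more, leaving out genes whose locus overlaps another listed locus on the same strand (408 rows), was chosen after seeing the data. Coordinates are those of the deposited loci on hg19; a locus can span several adjoining genes. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.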

Results

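Protein-coding expression was compared between 2 libraries of 231 breast cancer cells, 1 with the empty vector and 1 overexpressing HOXC-AS3, to find genes associated with this long non-coding RNA. HOXC-AS3 is transcribed from the minus strand of the HOXC homeobox cluster; GENCODE 29 places it at chromosome 12, 53981509 to 53985519 on GRCh38, overlapping the start of HOXC10. The tables held 1842 genes that were higher and 2089 that were lower in the HOXC-AS3 library than in the vector library, each by at least 2-fold in deposited FPKM. The estimated depth was 5390000 fragments in the HOXC-AS3 library and 5220000 in the vector library. With 1 library per group, no value below has a replicate error and no difference was tested against one. The level of HOXC-AS3 was not analysed here, so the overexpression was not checked.

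Genes differed in both directions between the libraries. On the scale of log2 of FPKM plus 1, 929 genes were at least 2-fold higher and 1003 at least 2-fold lower in the HOXC-AS3 library. Of all 3931 rows, 1275 (32.4%) were listed at 0 in 1 of the libraries, and the median FPKM in the higher library was 2.80 for the higher and 2.58 for the lower genes. In the authors' deposited table, the unadjusted p-value was under 0.05 for 826 genes and the adjusted p-value was under 0.05 for 49, of which 23 were higher and 26 lower. Of these 49, 39 were listed at 0 in 1 library.

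**Figure D1:**
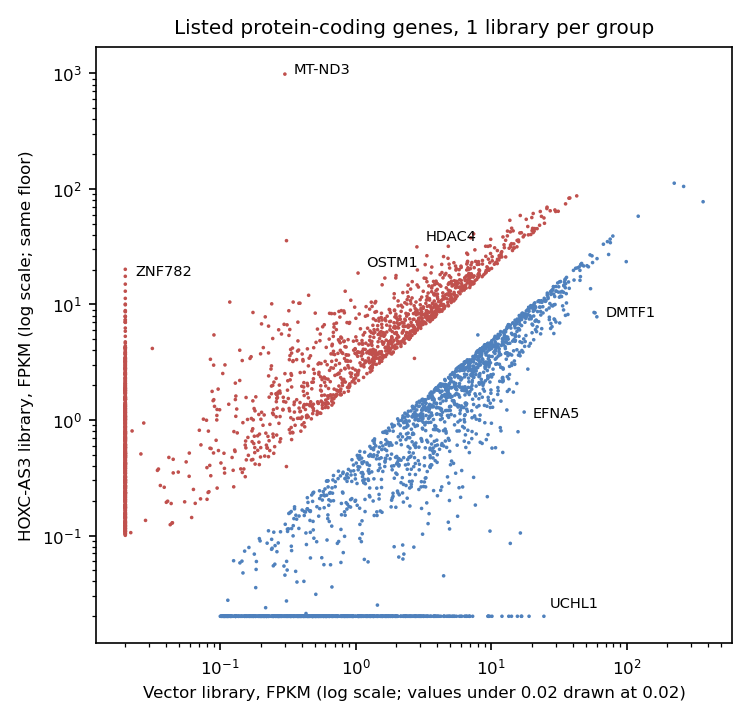
FPKM of every listed gene in the vector library (horizontal, log scale) and in the HOXC-AS3 library (vertical, log scale), with values under 0.02 drawn at 0.02. Genes higher in the HOXC-AS3 library are red and lower genes blue; the empty band along the diagonal reflects the authors' 2-fold limit (points inside it are symbols with several rows), and the rows along the edges are genes listed at 0 or next to 0, such as ZNF782 and UCHL1.

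The 12 largest log2 ratios among genes at FPKM 1 or more in both libraries lay between 2.31 and 3.27. OSTM1 (ENSG00000081087), which pairs with the lysosomal chloride transporter CLC7, had an FPKM of 1.04 in the vector library and 18.7 in the HOXC-AS3 library, the highest ratio. HDAC4, a class II histone deacetylase, was at 2.84 in the vector and 31.5 in the HOXC-AS3 library; pairs of values below follow the same order, vector first. PIAS4, a SUMO ligase, was at 4.84 and 31.8, and CRY2, a repressor of the circadian clock, at 2.86 and 19.9. LZTR1, an adaptor of a ubiquitin ligase that acts on RAS proteins, had an FPKM of 1.57 and 14.8. It shared its deposited locus with AIFM3, which was at 1.29 and listed at 0. How fragments of such genes were divided is not known, so the values of both are uncertain. COG3, a subunit of the Golgi tethering complex, was at 3.36 and 26.4, and the protein mannosyltransferase POMT2 at 3.26 and 22.1. BBIP1 and B9D2, both of the primary cilium, were at 7.43 and 40.8 and at 1.98 and 17.0. The zinc finger gene ZNF780B, the ubiquitin ligase gene RBBP6 and GATSL3 completed the 12, with FPKM in the HOXC-AS3 library of 17.8, 10.5 and 16.9. The locus of OSTM1 was chromosome 6, 108362612 to 108487058, and that of HDAC4 chromosome 2, 239969863 to 240324058 (hg19). In the authors' deposited table the adjusted p-value was 0.0133 for OSTM1 and 0.257 for HDAC4, and for the other 10 of these genes it was between 0.113 (LZTR1) and 0.748 (B9D2).

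The 12 smallest ratios lay between -3.09 and -2.30. EFNA5, which encodes the membrane ligand ephrin-A5, had an FPKM of 17.5 in the vector library and 1.17 in the HOXC-AS3 library, the lowest ratio. DMTF1, a transcription factor that activates the ARF tumour suppressor, was at 60.3 and 7.82. EPB41L1, a linker of membrane proteins to the actin cytoskeleton, was at 57.5 and 8.52, and COL7A1, the collagen of anchoring fibrils, at 10.3 and 1.29. ADARB1, an adenosine deaminase that edits RNA, was at 11.8 and 1.46. SPRTN, a protease that clears DNA-protein crosslinks, was at 13.6 and 1.83. ATF7IP, a partner of the histone methyltransferase SETDB1, was at 18.7 and 2.75, and the authors' deposited table gave it an adjusted p-value of 0.0133; for the other 11 genes of the 12 the authors' deposited table gave between 0.0581 (ADARB1) and 0.603 (DMTF1), with 0.0837 for EFNA5. C15orf40, PYROXD2, METTL21A, B4GALNT4 and GRAMD4 had vector FPKM of 58.5, 13.1, 14.6, 15.5 and 13.2 and were between 1.22 and 8.46 in the HOXC-AS3 library.

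Of the genes listed at 0 in 1 library, the 5 with the highest FPKM in the other are given for each direction. UCHL1, a neuronal ubiquitin hydrolase, was at 24.5 FPKM in the vector library and listed at 0 in the HOXC-AS3 library. GAGE12G, a cancer-testis antigen with near-identical copies, was at 16.8 and listed at 0, and the kinase gene MARK1 at 15.6 and listed at 0. RP11-680G10.1 and XXcos-LUCA11.5 were at 19.1 and 14.1 in the vector library and listed at 0 in the HOXC-AS3 library. In the other direction, the zinc finger gene ZNF782 was at 17.5 FPKM in the HOXC-AS3 library and listed at 0 in the vector library. ECSCR, an endothelial surface protein, SDSL, a serine dehydratase, and RNF32 were at 14.98, 13.0 and 11.3 there. AC062017.1, at 10.1, shared its deposited locus with HDAC4 on the opposite strand, and how fragments of such genes were divided is not given in the sources used here, so both values are uncertain. In the authors' deposited table the adjusted p-value was 0.0133 for UCHL1, SDSL and ZNF782 and 0.0251 for GAGE12G, and for the other 6 genes it was between 0.103 (RNF32) and 0.690 (AC062017.1).

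HOX genes are the homeobox transcription factors that set positional identity, and those with a row were mostly lower in the HOXC-AS3 library. Of the 39 HOX genes of the list, 17 were in the tables, 14 lower and 3 higher. Of the 8 at FPKM 1 or more in at least 1 library, 7 were lower. This share of higher genes (12.5%, exact binomial 95% interval 0.320 to 52.7) lay at percentile 2.51 of matched random lists. Over all 17, without the FPKM minimum, the share (17.6%) lay at percentile 0.850. That placement was made for no other list fixed in advance, and the genes it added were under FPKM 1 in both libraries. The median log2 ratio of the 8 was -1.29, at percentile 0.510, and that of all 17 was -0.63. All 4 HOXC genes present were listed at 0 in the HOXC-AS3 library, against vector FPKM of 4.79 for HOXC6, 1.97 for HOXC9, 1.08 for HOXC10 and 0.113 for HOXC8. They shared the deposited locus at chromosome 12, 54375292 to 54449814 (hg19). HOXB7 was at 6.35 in the vector and 1.79 in the HOXC-AS3 library, and HOXB3 at 3.35 and 0.192. HOXD1 went the other way, listed at 0 in the vector library and at 1.23 in the HOXC-AS3 library. In the authors' deposited table the adjusted p-value was 0.677 for HOXC6, 0.742 for HOXC9 and 0.312 for HOXB3, and 1 for HOXC10 and HOXC8. Most HOX rows shared deposited loci with neighbouring HOX genes; without genes in overlapping loci HOXD1 alone was left at FPKM 1 or more, and the share of higher genes was 100%.

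Of 26 genes on the transforming growth factor beta list 10 were in the tables and 16 had no row. All 9 with an FPKM of at least 1 were lower (0% higher, exact binomial upper limit 33.6%), at percentile 0.0800 of matched random lists, and 7 of them were at least 2-fold lower on the scale of log2 of FPKM plus 1. Their median log2 ratio of -1.19 lay at percentile 3.52. They included the shared signal transducer SMAD4 (26.8 in the vector and 9.31 in the HOXC-AS3 library), the SMAD repressor SKIL (13.0 and 4.71) and the ligand TGFB2 (34.5 and 14.5). The ligand TGFB3 was at 1.36 in the vector library and listed at 0 in the HOXC-AS3 library. ID2, a target of the related bone morphogenetic protein signals, named after its values were seen, was higher, listed at 0 in the vector and at 0.597 in the HOXC-AS3 library. The list holds activators and repressors of the pathway. Of the 9 lists with at least 5 members at FPKM 1 or more, 1 share, that of this list, was outside the central 95% of random lists. Chance nominally gives 0.450 lists. The HOX share lay just inside that range with the FPKM minimum. Without the minimum the HOX share lay outside, but no other of the 9 lists was placed that way. In the authors' deposited table the adjusted p-value was 0.355 for SMAD4, 0.489 for SKIL, 0.509 for TGFB2 and 1 for TGFB3.

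**Figure D2:**
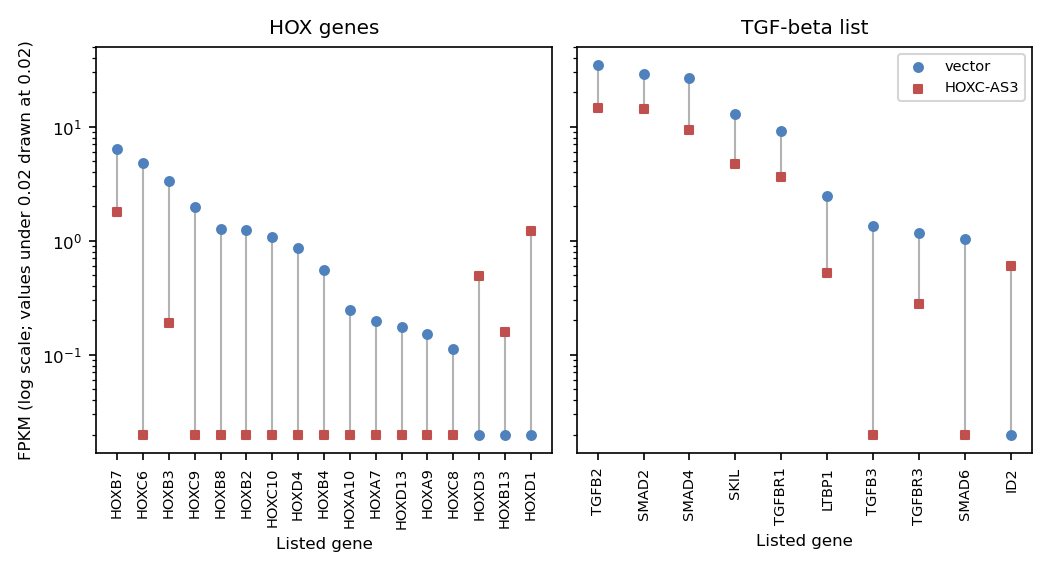
FPKM (log scale, values under 0.02 drawn at 0.02) of the listed HOX genes and of the listed genes of the transforming growth factor beta list, with the vector library as blue circles and the HOXC-AS3 library as red squares, 1 library each. Of the HOX genes 14 of 17 are lower in the HOXC-AS3 library, and of the second list 9 of 10.

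Extracellular matrix genes were found in both directions. Of 35 on the list 12 were in the tables, 8 lower and 4 higher; of the 6 at FPKM 1 or more, 4 were lower, and the median log2 ratio of -1.64 lay at percentile 1.22 of random lists while the share of higher genes (33.3%) lay at percentile 30.0. Without the FPKM minimum the median of the matrix list was -0.34. The laminin gene LAMA5 was at 10.1 in the vector and 2.36 in the HOXC-AS3 library, tenascin (TNC) at 10.8 and 3.04, and the basement membrane collagen COL4A5 at 4.25 and 0.246. The fibrillar collagen gene COL1A2 was higher, at 0.791 and 3.84, as was the proteoglycan lumican (LUM), at 0.346 and 3.26. Of the mesenchymal list, 3 of the 5 genes at FPKM 1 or more were higher, at percentile 67.5. SNAI1, a repressor of epithelial genes, was listed at 0 in the vector library and at 1.86 in the HOXC-AS3 library, while ZEB2, which has the same role, was at 3.22 and 0.401 and tropomyosin 2 (TPM2) at 9.86 and 1.40. Of 4 integrin genes at FPKM 1 or more 2 were higher, with ITGB6 at 0.659 and 3.74 and ITGA1 at 7.65 and 0.183. Of 4 matrix proteases at FPKM 1 or more 3 were higher. MMP17 was listed at 0 in the vector library and at 4.24 in the HOXC-AS3 library, and MMP9 was at 1.59 in the vector library and listed at 0. In the authors' deposited table the adjusted p-value was 0.0133 for MMP17 and 1 for MMP9, and among the other matrix, mesenchymal and integrin genes named here it was between 0.0944 (ZEB2) and 0.742 (ITGB6).

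Other lists held members in both directions. Of the zinc finger genes with a KRAB repressor domain, 15 of the 23 at FPKM 1 or more were higher (65.2%), at percentile 95.8; ZNF85 was at 0.643 and 8.38 and ZNF12 at 1.39 and 10.3, whereas ZNF26 was at 6.38 and 0.962. Of the interferon-stimulated genes 9 were present, 5 higher and 4 lower, and of the 5 at FPKM 1 or more 2 were higher (percentile 38.1). The antiviral GTPase MX1 was at 2.54 in the vector and 10.8 in the HOXC-AS3 library, while IFI44 was at 11.8 and 0.805 and DDX60 at 6.17 and 0.263. In the NOTCH pathway 3 of 7 were higher (percentile 41.2), with RFNG at 13.2 and 39.2 and the coactivator MAML1 at 14.2 and 2.97. Of the histone and DNA methylation enzymes 7 were present, 4 higher and 3 lower. Of the 6 at FPKM 1 or more 3 were higher (percentile 52.9), with the demethylase KDM6A at 6.49 and 14.7 and the Polycomb subunit SUZ12 at 5.39 and 1.36. Of 7 listed immediate early genes, 5 were lower, among them all 4 at FPKM 1 or more, with KLF2 at 12.3 and 2.76 and JUND at 75.6 and 36.7. Of the very long genes, kept as a check of RNA length, 2 of 8 were higher (percentile 8.82), with UTRN at 15.8 and 0.791 and NBEA at 0.202 and 6.79.

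Several lists of basic cell functions had few or no rows, and genes without a row may have differed by less than 2-fold or been under the authors' FPKM limit. None of 44 ribosomal protein genes, 38 nuclear genes of oxidative phosphorylation, 35 proteasome genes and 31 NF-kB and inflammatory genes had a row. Of 30 genes on the mitosis list, only BUB1B did (23.5 in the vector and 10.8 in the HOXC-AS3 library). Of 30 genes on the DNA replication list 4 did, all lower. Among them were the chromatin assembly gene CHAF1A at 27.1 and 10.2 and cyclin E2 (CCNE2) at 11.3 and 5.14. These lists are short and hold only part of each function. At FPKM 1 or more, the annotation term mitotic nuclear division held 28 listed genes, 7 higher and 21 lower. DNA replication held 26, 8 higher and 18 lower, and inflammatory response held 34, 17 higher and 17 lower. Of the hypoxia and glycolysis genes only PFKFB4 was present, at 28.5 and 9.70. Of the mitochondrially encoded genes only MT-ND3 had a row, at 0.301 in the vector and 985 in the HOXC-AS3 library. The other 12 had no row. Whether the MT-ND3 values reflect expression or a failed estimate was not tested, so they are uncertain. Of 32 lipid synthesis genes 2 were present, both higher, and the fatty acid elongase ELOVL6 was at 9.84 and 32.2. Of 4 p53 targets at FPKM 1 or more 1 was higher, with the p53 antagonist MDM2 at 20.6 and 7.94 and the death receptor gene FAS at 0.712 and 2.98. Of 28 NRF2 and metallothionein genes 6 were present, 3 higher and 3 lower. Of the 4 at FPKM 1 or more 1 was higher, with the glutathione synthesis gene GCLM at 25.6 and 8.97 and the transporter gene ABCC2 at 0.238 and 2.76. Of 24 m6A and RNA-binding regulators 3 were present, all lower; the m6A reader IGF2BP2 was at 34.4 and 14.7, and IGF2BP1 of the same family at 1.35 and listed at 0.

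Markers of other cell types were found in both directions. None of the 15 luminal breast markers had a row. Of 13 basal and myoepithelial markers 2 were present, both higher, and OXTR was at 3.73 in the HOXC-AS3 library and listed at 0 in the vector library. Of 18 blood cell markers 4 were present, 1 higher and 3 lower, and of 14 hepatocyte or neural markers 6 were, 3 higher and 3 lower; the members at FPKM 1 or more were lower. The B cell receptor gene CD79A was at 2.05 in the vector library and listed at 0 in the HOXC-AS3 library, the monocyte marker CD14 was at 1.59 and 0.359, and the glial filament gene GFAP was at 2.66 and listed at 0. Of 10 endothelial markers 2 were present, both lower and both under FPKM 1. Of 26 epithelial genes 6 were present, 2 higher and 4 lower, with the surface protein gene EPCAM at 6.34 and 3.17 and the splicing regulator gene ESRP2 at 0.531 and 1.39.

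**Figure D3:**
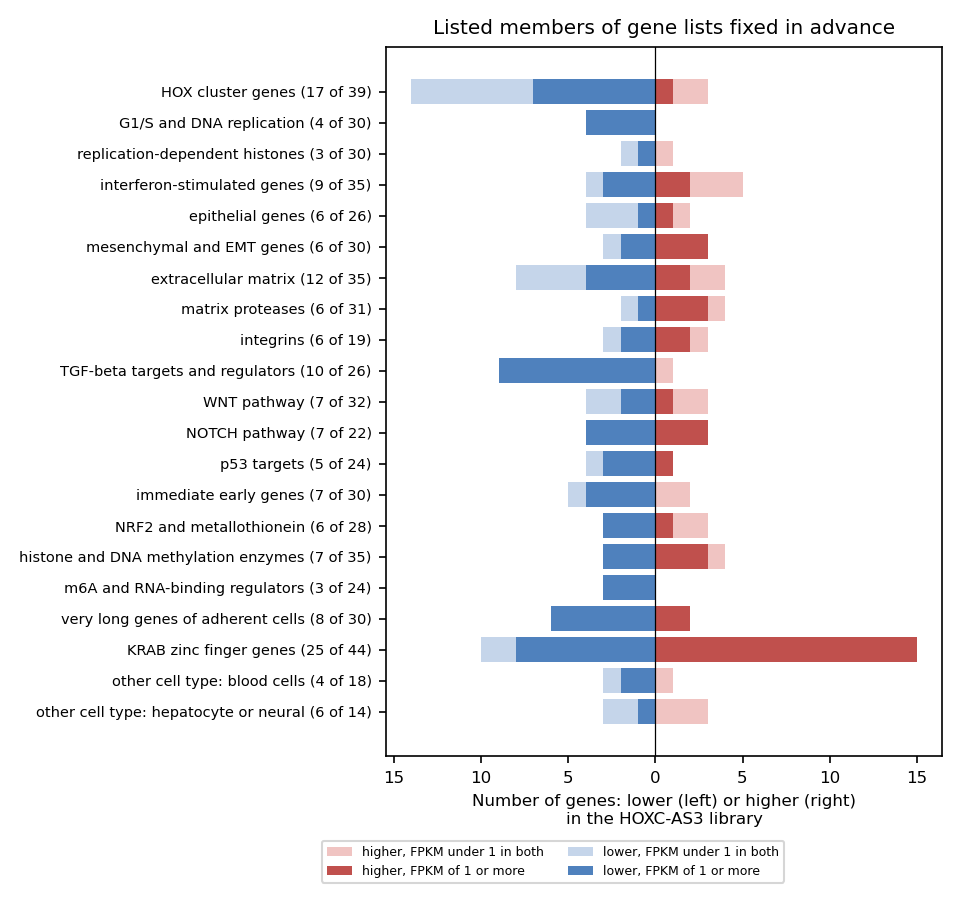
Number of listed members that were higher (right, red) or lower (left, blue) in the HOXC-AS3 library, for lists with at least 3 members in the tables; labels give the members present and the size of the list, and pale bars are genes under FPKM 1 in both libraries. Of the genes of the transforming growth factor beta list at FPKM 1 or more, 9 of 9 are lower, and of the KRAB zinc finger genes 15 of 23 are higher.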

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

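Leaving out genes whose locus overlaps another listed locus on the same strand was chosen after seeing the data; the other settings were planned. The numbers of genes at least 2-fold higher and lower moved most with the FPKM minimum and the fold. With an FPKM of at least 5 in at least 1 library, 534 genes were higher and 551 lower; with at least 1 in both libraries, 515 and 537; with a fold threshold of 4, 147 and 156. The other 6 settings kept each count within 1.5 times. A pseudocount of 0.1 raised the counts to 1262 higher and 1366 lower, and a pseudocount of 0.01 to 1289 and 1405. Having no minimum moved nothing, since a gene under FPKM 1 in both libraries cannot reach 2-fold with a pseudocount of 1. The handling of repeated symbols could touch few genes. With a minimum of 5 the share of higher members was 0% for the HOX, mesenchymal and extracellular matrix lists, with fewer members left. HOXB7 alone was left of the HOX list and TPM2 alone of the mesenchymal list, so their medians at that minimum are the ratios of single genes. Without overlapping loci the HOX share was 100% and its median 1.16, because HOXD1 alone was left. The other 41 list shares, those of the transforming growth factor beta list included, stayed within their 95% binomial intervals. This says little about stability. A pseudocount keeps every sign and so cannot move a share, and only 6 symbols were repeated. The intervals were also wide, such as 5.27% to 85.3% for the interferon list. The HOX median log2 ratio was -3.66 with a pseudocount of 0.1 and -0.63 without a minimum, and the extracellular matrix median was -0.34 without a minimum. Medians of the opposite sign to the main value were also found for the interferon list (0.34 without a minimum, main value -0.45), the mesenchymal list (-2.18 with a minimum of 5, main value 0.58) and the NOTCH list (0.08 with a minimum of 5 and 0.03 without overlapping loci, main value -0.63). The transforming growth factor beta median was -1.52 with a pseudocount of 0.1. Of the 38 genes named for their size, for a value of 0 or as HOXC genes, 19 had ratios that moved by over 1.5 times with a pseudocount of 0.1, OSTM1 to 4.04 and EFNA5 to -3.80 among them; a pseudocount cannot turn a sign, and the other named list members were not recomputed. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. A fold threshold of 1.5, median centring and trimmed mean scaling were not run, since genes under 2-fold were not analysed here, and the level of HOXC-AS3 was not analysed here. Of 333 genes with 1 annotated transcript, the exact 95% binomial interval of the estimated fragment counts excluded equal levels in 197 (59.2%) and every ratio under 2 in 83 (24.9%); these genes had been selected for a 2-fold difference in the same values, so the shares do not give how many differed beyond counting error. The median gene had 10 fragments over both libraries.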

Other observations

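The tests of counting error and of another stock for the HOX and MAGEA genes, and of reads shared between MAGEA copies, were chosen only after the result was seen, as were the 6 gene families looked at; the test of copy number was planned, but how to read it was revised after its result was seen.

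The listed cancer-testis antigens of the MAGEA family, genes of the X chromosome normally silent outside the germ line, were all lower in the HOXC-AS3 library. All 7 listed members were at 0 there. In the vector library MAGEA4 was at 5.32 FPKM, MAGEA12 at 2.34 and MAGEA6 at 1.87, and the authors' deposited table gave an adjusted p-value of 0.0133 for MAGEA4, 0.0613 for MAGEA12, 0.0972 for MAGEA6 and 1 for the other 4 members. With the FPKM minimum of 1 the share of higher members (0 of 3) lay at percentile 6.12 of random lists matched on expression, inside the central 95% range, and without a minimum (0 of 7) at percentile 0.630. Of the MAGE genes of any subfamily, 5 of 5 were lower with the minimum (percentile 1.52) and 10 of 12 without it (percentile 1.98), and both listed GAGE genes were lower. In the other 3 families looked at, with the minimum, 76 of 161 ZNF genes (percentile 46.5), 16 of 41 SLC genes (percentile 12.1) and 0 of 1 PCDHG genes were higher; without it the ZNF share, 85 of 203, lay at percentile 8.32. Of 77 listed genes of the X chromosome at FPKM 1 or more, MAGEA genes included, 26 were higher (33.8%, percentile 0.780 of shuffled directions), of 111 on chromosome 5 41 were (36.9%, 0.960) and of 132 on chromosome 16 77 were (58.3%, 99.4). These were 3 of 23 chromosomes outside the central 95% range, where chance gives 1.15. Of 212 annotation terms 9 lay outside that range, where chance gives 10.6. Of these terms 7 lay below the range, mitotic nuclear division (percentile 0.57) among them, and 2 above it.

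HOX genes (14 of 17 lower) and MAGEA genes (7 of 7 lower) were set beside counting error at the estimated depth. Fragments were estimated with the shortest annotated transcript of each gene, so the counts and the weight of each gene depend on that choice. The HOX genes held an estimated 70 fragments in the vector and 22 in the HOXC-AS3 library. The vector share was 76.1% (exact 95% interval 66.1 to 84.4), and without HOXB4, whose removal lowered the limit most, 73.2%. The FPKM of the same HOX genes summed to 22.3 in the vector and 3.86 in the HOXC-AS3 library. The MAGEA genes, without 1 that had no annotated length, held 61 and 0, a share of 100% (lower limit 94.1%). These shares do not exclude counting error, since all listed genes had been selected for differing by 2-fold and the MAGEA family was picked because its members were listed at 0. For the same reason the sums of the listed MAGEA genes, 12.02 FPKM in the vector library and 0.0 in the HOXC-AS3 library, leave reads shared between near-identical copies open. With 1 library per group, another stock or clone of the line cannot be told apart from an effect of HOXC-AS3, and since LIAS was also listed at 0, failed estimates stay possible for the genes at 0.

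Neighbouring listed genes under 500 kb apart had the same direction slightly more often than shuffled directions (52.97% of 1365 pairs, percentile 98.4). Among pairs at least 500 kb apart the share was 50.46% (percentile 59.9; the central 95% of shuffled directions ended at 53.04%). Large regions of different copy number stay open, because the share seen under 500 kb would also have lain inside that range, so the bound set in advance could not exclude them, and 3 chromosomes were off balance. Fragments shared between adjoining gene models were not decided either: the share was 49.58% in overlapping pairs (percentile 44.4), 53.26% in pairs up to 50 kb apart (percentile 91.5), 51.55% in pairs at least 50 kb apart (percentile 90.5) and 51.86% over all non-overlapping pairs (percentile 96.1), all inside the central 95% range. Of 6 distance classes looked at, only the class under 500 kb lay above the central 95% range.

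Estimates between 0 and 1e-04 FPKM in 1 library occurred in 113 rows. Of these 48.7% overlapped another listed locus on the same strand, against 10.4% of all rows, 8.5% of rows at exactly 0 and at most 15.9% in the central 95% of random sets. This is consistent with fragments being assigned to the other of the overlapping gene models, so large ratios of such rows may reflect assignment and not expression. Of 86 overlapping pairs with such a row, 52 had opposite directions and 34 the same. No biological explanation was tested.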
